A study of Homo sapiens with 9 samples.

How the data were processed

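Total RNA of BeWo cells was extracted with Isogen, turned into biotin-labelled single-stranded cDNA with the GeneChip WT Plus kit and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds log2 values, 1 per probe set and array, for 9 arrays and 70523 rows. The authors made these log2 values with RMA, per the submitters' processing notes; RMA corrects background, normalizes quantiles between arrays and summarises probes, and its software and version are not given in the sources used here. The log2 scale was read from the values, which ran from 1.38 to 14.3. Quantile normalization sets the arrays to nearly one distribution, so a change of total RNA per cell would not be seen, and the summary compresses changes of dim genes, which understates folds there. No array scan files were used here.

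Arrays were grouped by the treatment in the labels into untreated cells, cells given the EPAC-selective analog and cells given the PKA-selective analog, 3 arrays each, all at 48 h. Rows were named through the array annotation held by GEO, which can be old: 23781 rows had 1 gene symbol, 1543 had several and 45199 were not listed. Rows with several symbols or none were named for no gene. Of the rows with 1 symbol, 21497 were matched by Entrez number to a RefSeq gene table, and 0 symbols changed. The probe set with the highest mean over all 9 arrays stood for its gene, which left 22465 genes; 479 genes had more than 1 row, and 35 genes had values equal in all 9 arrays to those of another gene. CGB3 and CGB5, beta subunits of chorionic gonadotropin, were reached only by probe sets with several symbols, and RAPGEF4, which encodes EPAC2, was not in the annotation used here, so no value is given for them. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed.

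Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend) on all 9 arrays, with 6 residual degrees of freedom, 3 comparisons and Benjamini-Hochberg adjustment over all genes of a comparison, at an adjusted p of 0.05. Values are given as log2 changes with the standard error of the fit. No filter on dim genes was applied. The 22 gene lists were written from textbook knowledge before the data were examined and hold 423 distinct genes, of which 384 were measured and 9 are in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, then with the correlation estimated and with fry, which tests whether the members of a list move on balance one way. Calls within a list are counted over all genes and adjusted over the list alone. The rule for naming genes was also set before: per comparison, the 10 largest and 10 smallest log2 changes among genes past the threshold whose arrays did not overlap between the groups, or the 5 smallest p-values per direction if none passed; 12 genes fixed in advance; and up to 4 members per list. MicroRNAs, small nucleolar RNAs, antisense and uncharacterised transcripts were passed over by that rule. KLHDC7B in the paragraph on both analogs, HLA-G, GCM1 beside its list, EBI3, TOP2A, CCR7 and the members of lists named with the EPAC-selective analog were singled out after their values were seen, as were MIR222 and MIR21.

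The fit and the list tests were checked on simulated data with 22465 genes, with many genes changed at once and noise independent between genes. For the EPAC comparison 100 of 100 genes changed by 0.5 log2 and 35 of 100 changed by 0.25 log2 were recovered with 5 false calls, and for the PKA comparison 96 of 100 changed by 0.5 and 100 of 100 changed by 1 log2 with 9 false calls. For the direct comparison 98 of 100 genes changed by 0.5 log2 and 44 of 100 changed by 0.25 log2 were recovered with 5 false calls. Of 100 lists of 20 genes, the 1 shifted by 0.2 log2 passed in camera, with 0 false lists, at the preset and the estimated correlation. Noise independent between genes cannot test the preset of 0.01, since the correlation estimated on the real arrays reached 0.557 for mitosis genes. The correlation of both comparisons against the shared untreated arrays was set beside 100 simulations that keep the correlations between genes. Alternatives fixed before the data were examined were the replicate number as a block, only the groups compared, an intensity trend, robust eBayes, array weights, another round of quantile normalization, centring on array medians, filters on dim genes, the mean of a gene's probe sets, all rows of the table, at least a 1.5-fold change, the estimated correlation, fry, and each array left out in turn. The 25th percentile of each array as a covariate, an unadjusted threshold and the simulated noise that keeps gene correlations were added after seeing the data, as were 3 gene lists used in the closing section. A gene value that changed sign was treated as a reversal where it was past the threshold in either fit. For lists the direction of the test was compared in the same way, and for the correlation the sign alone. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.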

Results

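The series holds 9 Affymetrix arrays of BeWo cells, a human choriocarcinoma line that stands in for the placental trophoblast in culture. Its cells fuse and begin to make placental hormones when cyclic AMP rises. Cells of 3 arrays were left untreated, cells of 3 arrays received an EPAC-selective cyclic AMP analog and cells of 3 arrays a PKA-selective analog, all for 48 h. EPAC proteins are exchange factors that activate the small GTPase Rap. PKA is the cyclic AMP-dependent protein kinase. The comparisons ask which genes each branch of cyclic AMP signalling alters. The EPAC-selective compound carries a chlorophenylthio group at position C8 and a methyl group on the ribose oxygen, whereas the PKA-selective compound carries a phenyl group on the N6 nitrogen. The doses are not given in the sources used here. Array medians lay between 4.85 and 4.96 on the log2 scale, and arrays of one group correlated at 0.996 to 0.997 across all 70523 rows. Nothing in the labels says whether the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

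The PKA-selective analog raised single genes of placental hormones, steroid enzymes and fusion proteins above their level in untreated cells and lowered others. CGA, the alpha subunit of chorionic gonadotropin, rose 5.00-fold, by 2.32 ± 0.056 on the log2 scale (SE, n = 3 arrays per group, adjusted p = 4.96e-09). The galectin gene LGALS16 rose 6.05-fold and HSD11B2, the enzyme that inactivates cortisol, 4.99-fold. ERVFRD-1, which encodes the fusogenic envelope protein syncytin-2, rose 4.31-fold. In the opposite direction, SLC7A11, which encodes the light chain of the cystine and glutamate exchanger, fell by 2.58 ± 0.246 and ASS1, argininosuccinate synthase, fell by 1.89 ± 0.041 log2.

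Of 22465 genes tested, 5031 passed an adjusted p of 0.05 in limma, 2336 higher and 2695 lower with the PKA-selective analog, and most changes were small. At least a 2-fold difference was reached by 49 of the higher and 53 of the lower genes. In 35.6% of all genes the 3 treated arrays lay entirely above or below the 3 untreated ones, where chance gives 10%. The median log2 change over all genes was 0.04.

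The 10 largest increases, chosen among genes whose arrays did not overlap between the groups, went on with PADI1, a peptidylarginine deiminase, at 2.24 ± 0.068 log2, and with ERVV-2, an endogenous retroviral envelope gene, at 2.15 ± 0.122. SLC7A8, a neutral amino acid transporter, rose by 1.90 ± 0.051, LEP, the hormone leptin, by 1.86 ± 0.124, FSTL3, a secreted activin antagonist, by 1.85 ± 0.076, and TREML2, a cell surface receptor, by 1.75 ± 0.081. MicroRNA genes, among them MIR222 and MIR21 given further below, and the other classes passed over in naming were left out of both rankings. The 10 largest decreases thus chosen included the mitochondrial folate enzyme ALDH1L2, which fell by 1.82 ± 0.123. The transcription factor TFCP2L1 fell by 1.82 ± 0.051. CCDC141 fell by 1.75 ± 0.079 and TTN, which encodes titin, fell by 1.72 ± 0.073. ASNS, asparagine synthetase, fell by 1.68 ± 0.184, and the phosphate transporter SLC34A2 fell by 1.66 ± 0.098. ULBP1, a ligand of the NKG2D receptor, fell by 1.64 ± 0.187, and BCAT1, which transaminates branched-chain amino acids, fell 2.83-fold. Adjusted p-values of these 20 genes ran from 3.41e-09 for ASS1 to 0.000110 for ULBP1. The treated arrays of SLC7A11, ASNS and ULBP1 spread widely, with SDs of 0.67, 0.50 and 0.51 log2, while their untreated arrays had SDs of 0.12, 0.07 and 0.08.

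**Figure D1:**
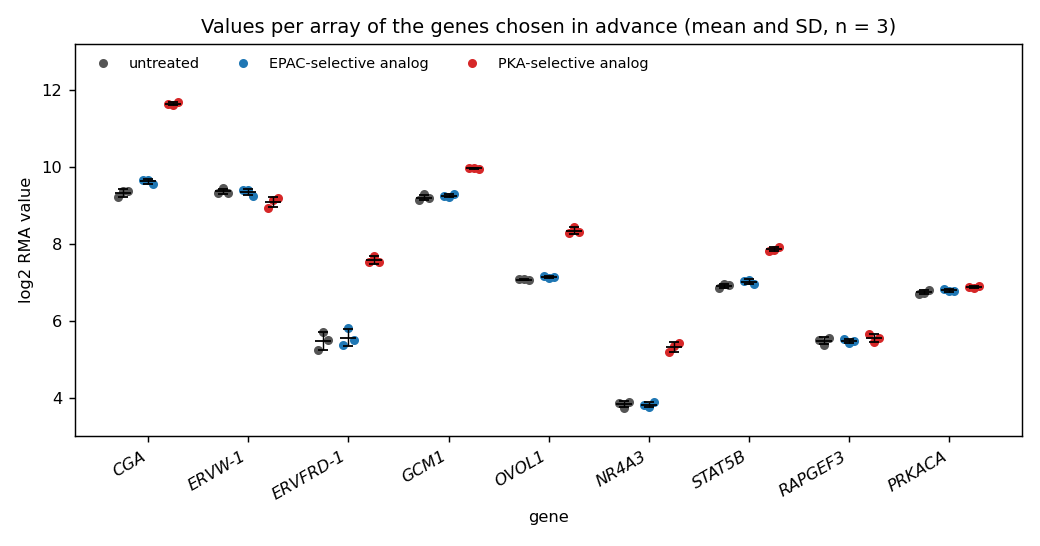
Values per array on the log2 scale of the 9 measured genes that were chosen for naming in advance; points are single arrays, and black marks give the mean with its SD for 3 arrays. CGA stood at 9.32 untreated, 9.62 with the EPAC-selective analog and 11.64 with the PKA-selective analog, while RAPGEF3 and PRKACA moved little.

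Markers of the syncytiotrophoblast, the fused hormone-making layer of the placenta, rose together with the PKA-selective analog. Among the placental protein hormones, 8 of 12 measured genes rose and 0 fell, against 8 higher and 2 lower when adjusted over the list alone. Their median was 0.39 log2 (camera adjusted p = 3.55e-05, but adjusted p = 0.0901 with an estimated correlation). Besides CGA and LEP, INSL4, an insulin-like placental peptide, rose by 1.05 ± 0.070, and ADM, the vasodilator adrenomedullin, by 0.71 ± 0.055. INSL4 was dim, at 3.51 to 3.65 log2 untreated and 4.49 to 4.75 treated, below the array medians in both groups. Of the pregnancy-specific glycoproteins, 8 of 9 rose, or 9 adjusted over the list alone, at a median of 0.32 log2 (camera adjusted p = 4.63e-06, and adjusted p = 0.0425 with an estimated correlation). PSG9 rose by 0.78 ± 0.070, PSG4 by 0.67 ± 0.053, PSG1 by 0.43 ± 0.051 and PSG3 by 0.33 ± 0.049. Probes of this near-identical family may read several members, so single values are uncertain, and PSG1 lay below the array medians in both groups. Of 23 other syncytiotrophoblast markers 14 rose and 1 fell, with the same counts adjusted over the list alone. Their median was 0.22 log2 (camera adjusted p = 8.07e-08, and adjusted p = 0.0344 with an estimated correlation), and it ran from 0.19 to 0.61 over 21 other settings. LGALS16 and HSD11B2 led this list, followed by the retroviral envelope gene ERVV-1 at 1.68 ± 0.122 and the aromatase gene CYP19A1 at 1.64 ± 0.062.

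Fusion proteins and their receptors split. Of 13 measured genes 5 rose and 3 fell, or 6 and 3 adjusted over the list alone, and camera did not call the list (median 0.09 log2, camera adjusted p = 0.368), while fry, which does not set a list against the other genes, did (adjusted p = 0.000626). ERVV-2, ERVFRD-1 and ERVV-1 rose by 2.15, 2.11 and 1.68 log2, whereas SLC1A5, a neutral amino acid transporter that serves as the receptor of syncytin-1, fell by 1.10 ± 0.105. ERVW-1, which encodes syncytin-1, fell by 0.28 ± 0.070 (adjusted p = 0.0136). Without the replicate 2 array of the untreated cells its value was -0.24 and the call was lost, as it was at -0.21 with each array's 25th percentile as a covariate, a setting chosen after seeing the data. With array weights it stood at -0.17, still called. Among the trophoblast transcription factors 12 of 21 rose and 0 fell, with 12 adjusted over the list alone (median 0.24 log2, camera adjusted p = 7.65e-07, but adjusted p = 0.0901 with an estimated correlation). The nuclear receptor NR4A3 rose by 1.49 ± 0.065, OVOL1, a zinc finger repressor, by 1.27 ± 0.047, STAT5B by 0.96 ± 0.048 and the homeobox gene DLX4 by 0.81 ± 0.054. GCM1, which drives syncytin expression in trophoblast, rose by 0.76 ± 0.045 (adjusted p = 1.15e-06).

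Steroid and sterol genes rose as well. Of 11 steroid synthesis genes 7 rose and 0 fell, or 9 adjusted over the list alone (median 0.41 log2, camera adjusted p = 8.07e-08, but adjusted p = 0.0590 with an estimated correlation). This list shares HSD11B2 and CYP19A1 with the syncytiotrophoblast markers. SCARB1, a receptor that takes up lipoprotein cholesterol, rose by 0.85 ± 0.057, and CYP11A1, which makes pregnenolone from cholesterol, by 0.85 ± 0.055. Of 19 genes of cholesterol synthesis and uptake 10 rose and 1 fell, or 13 and 1 adjusted over the list alone (median 0.21 log2, camera adjusted p = 2.08e-05, but adjusted p = 0.201 with an estimated correlation). HMGCS1 rose by 0.71 ± 0.072, INSIG1 by 0.69 ± 0.045, SQLE by 0.48 ± 0.050 and DHCR7 by 0.33 ± 0.057. In the list of hypoxia and glycolysis genes 14 of 19 rose and 1 fell, or 15 and 2 adjusted over the list alone (median 0.30 log2, camera adjusted p = 7.65e-07, but adjusted p = 0.0901 with an estimated correlation). NDRG1 rose by 1.56 ± 0.046, the glucose transporter SLC2A1 by 1.14 ± 0.044, and the mitophagy gene BNIP3 by 0.59 ± 0.049.

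Targets of the cyclic AMP response element also rose. Of 25 measured genes 12 rose and 1 fell, with the same counts adjusted over the list alone (median 0.11 log2, camera adjusted p = 4.74e-07, and adjusted p = 0.0200 with an estimated correlation). Apart from NR4A3, the phosphatase DUSP1 rose by 1.04 ± 0.049, the kinase SIK1 by 0.92 ± 0.039 and FOS by 0.90 ± 0.046. Markers of the extravillous trophoblast, the invasive lineage of the placenta, rose in 13 of 21 cases and fell in 0, or in 14 and 1 adjusted over the list alone (median 0.25 log2, camera adjusted p = 2.83e-08, and adjusted p = 0.0192 with an estimated correlation). LAIR2, a soluble collagen receptor, rose by 1.63 ± 0.046, the protease ADAM19 by 0.95 ± 0.046, fibronectin FN1 by 0.82 ± 0.043 and the gelatinase MMP2 by 0.71 ± 0.041. HLA-G, a leading marker of that lineage, differed by 0.03 ± 0.057 (adjusted p = 0.755). Cytotrophoblast and stem cell markers went both ways, with 6 of 19 higher and 5 lower over all genes and adjusted over the list alone. The list showed no shift past the threshold, and its median differed in sign from its mean and test (median 0.03 and mean -0.01 log2, camera adjusted p = 0.521). EGFR and ID2 rose by 0.66 ± 0.044 and 0.56 ± 0.050, while the integrin ITGB4 fell by 0.64 ± 0.046 and YAP1 fell by 0.52 ± 0.050.

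Epithelial junction genes were the only list of the 22 that passed in the downward direction. Of 18 measured 7 fell and 3 rose, with the same counts adjusted over the list alone (median -0.11 log2, camera adjusted p = 0.00378, but adjusted p = 0.208 with an estimated correlation). The tight junction gene OCLN fell by 1.05 ± 0.067, EPCAM fell by 0.76 ± 0.054, TJP1 fell by 0.75 ± 0.072 and CLDN3 fell by 0.38 ± 0.055. Genes of DNA replication and the entry into S phase rose in 7 of 22 cases and fell in 0, or rose in 8 adjusted over the list alone (median 0.10 log2, camera adjusted p = 0.00720, but adjusted p = 0.470 with an estimated correlation). RRM2 rose by 0.61 ± 0.043, CCNE1 by 0.55 ± 0.039, FEN1 by 0.48 ± 0.075 and ORC1 by 0.45 ± 0.048. The list's call was lost without the replicate 2 array of the PKA-selective analog, where its median was 0.06. Of 23 mitosis genes 10 rose and 3 fell, or 11 and 3 adjusted over the list alone (median 0.10 log2, camera adjusted p = 0.0699). Whether the mitosis list passed depended on the setting. It passed with quantiles normalized again (adjusted p = 0.0102), over every row of the table (0.0230), without untreated replicate 2 or PKA-selective replicate 1 (0.00503 and 0.00276, each at a median of 0.14) and with the 25th percentile covariate (3.73e-05, median 0.18), but not with an estimated correlation (adjusted p = 0.690). CCNB1 and DLGAP5 each rose by 0.39 log2 and KIF20A and AURKB by 0.32 log2. Of 6 CDK inhibitors 1 rose, or 2 adjusted over the list alone: CDKN1A, which encodes p21, by 0.54 ± 0.043 (list median 0.11 log2, camera adjusted p = 0.0638). That list passed in 5 other settings, namely fry (adjusted p = 0.000133), every row of the table (0.0230), centred arrays (0.0491), the 25th percentile covariate (0.0367) and without PKA-selective replicate 1 (median 0.08, adjusted p = 0.0475), and had an adjusted p = 0.201 with an estimated correlation.

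The remaining lists were not past the threshold in camera with the PKA-selective analog, though fry called 4 of them. Of 26 nutrient and drug transporters 11 rose and 7 fell, or 11 and 8 adjusted over the list alone (median 0.05 log2, camera adjusted p = 0.180, fry adjusted p = 3.04e-05). Beside SLC7A8, the serotonin transporter SLC6A4 rose by 1.37 ± 0.051, the iron exporter SLC40A1 by 1.16 ± 0.051 and the transferrin receptor TFRC by 0.86 ± 0.049. Unfolded protein response genes split into 8 higher and 7 lower of 21, or 8 and 9 adjusted over the list alone (median -0.00 and mean -0.15 log2, camera adjusted p = 0.521). Those that fell most, ASNS, TRIB3 at -1.23 ± 0.052 and CHAC1 at -0.99 ± 0.224, also answer to amino acid shortage, while the chaperone CALR rose by 0.93 ± 0.047. CHAC1 moved to -0.66 without replicate 1 of the PKA-selective analog and to -0.52 with array weights, still past the threshold, and its call was lost, at -0.76, with the 25th percentile covariate. Among 20 interferon-stimulated genes 1 rose and 2 fell, with the same counts adjusted over the list alone (median 0.04 log2, camera adjusted p = 0.969). RSAD2, below the array medians in both groups, rose by 0.62 ± 0.081, IFI6 fell by 0.80 ± 0.040 and HERC5 fell by 0.23 ± 0.059. Of 20 EPAC and Rap signalling genes 2 rose and 6 fell, or 3 and 6 adjusted over the list alone (median -0.01 log2, camera adjusted p = 0.105, fry adjusted p = 0.000626). The phospholipase PLCE1 fell by 0.63 ± 0.052, RAPGEF2 fell by 0.43 ± 0.063, SIPA1L1 fell by 0.34 ± 0.058 and RAPGEF6 fell by 0.29 ± 0.058. RAPGEF3, which encodes EPAC1, differed by 0.07 ± 0.062 (adjusted p = 0.428). The list of PKA subunits, inhibitors and anchoring proteins also holds CREB1 and CREBBP, which are none of these and were the 2 that fell. Of its 18 genes 3 rose and 2 fell, or 3 and 3 adjusted over the list alone (median 0.05 log2, camera adjusted p = 0.969). AKAP12 rose by 0.38 ± 0.053, PKIB by 0.16 ± 0.046 and PRKACA, a catalytic subunit, by 0.14 ± 0.043 (adjusted p = 0.0405), while CREBBP fell by 0.30 ± 0.054 and CREB1 fell by 0.24 ± 0.063.

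Markers of stromal, endothelial and blood cells rose in 4 of 17 cases and fell in 0, with the same counts adjusted over the list alone (median 0.06 log2, camera adjusted p = 0.0622). This list passed in 7 of 21 other settings, among them every row of the table (adjusted p = 0.0185), genes above the median of all rows (0.0215, median 0.19), centred arrays (0.0491) and fry (0.0245), and without untreated replicate 3 (0.10, adjusted p = 0.0362) or PKA-selective replicates 2 (0.09, adjusted p = 0.0422) or 3 (0.08, adjusted p = 0.0438). With the 25th percentile covariate its median was -0.00, and with an estimated correlation it did not pass (adjusted p = 0.514). CDH5, already high in untreated cells at 10.82 log2, rose by 0.38 ± 0.040, PDGFRB by 0.36 ± 0.042, VWF by 0.20 ± 0.055 and CD68 by 0.19 ± 0.043. Housekeeping genes rose in 3 of 9 cases and fell in 2, or in 4 and 2 adjusted over the list alone (median -0.03 log2, camera adjusted p = 0.726, fry adjusted p = 0.0422). Their mean was 0.06 and the test pointed upward, and the median turned to 0.04 when quantiles were normalized again. SDHA rose by 0.44 ± 0.042, TOP1 by 0.27 ± 0.052 and GAPDH by 0.20 ± 0.040, while HPRT1 fell by 0.25 ± 0.046. Small calls depended on single arrays. With 1 array left out of the fit, that of PRKACA was lost without 8 of the 9 arrays, all but replicate 3 of the untreated cells, at 0.12 to 0.15 log2. That of VWF was lost at 0.14 to 0.19 log2 without untreated replicate 2 or without PKA-selective analog replicates 1 or 3. That of CREB1 was lost at -0.24 to -0.19 without untreated replicates 1 or 2 or treated replicates 1 or 3. The call of PKIB was lost at 0.13 to 0.15 without untreated replicates 1 or 3 or treated replicates 2 or 3, and the call of HERC5 at -0.22 to -0.19 without untreated replicates 1 or 2 or treated replicate 1. When every row of the table was tested, these 5 calls were lost as well. PRKACA, VWF and PKIB were also lost in fits of only the groups compared. With arrays centred on their medians PRKACA at 0.11 and PKIB at 0.13 were lost, and PKIB also at 0.15 with quantiles normalized again. With the 25th percentile covariate PRKACA and VWF stood at 0.12, no longer called, while CREB1 at -0.16 and HERC5 at -0.15 were still called.

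With the EPAC-selective analog differences from untreated cells were small, and no single gene passed the test. GDF15, a stress-induced cytokine, stood 1.25-fold higher, at 0.32 ± 0.042 log2 (SE, n = 3 arrays per group, adjusted p = 0.113), and CGA 1.23-fold higher, at 0.30 ± 0.056 (adjusted p = 0.201). Among gene groups, extravillous trophoblast markers were higher as a list, at a median of 0.07 log2 over 21 genes (adjusted p = 0.0126 with an estimated correlation). Mitosis genes stood at a median of -0.08 log2 over 23 genes (adjusted p = 0.376 with an estimated correlation).

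Of the 22465 genes 0 passed in limma, with 1096 at an unadjusted p under 0.05, where 1123 are expected by chance. In 10.0% of genes the arrays of the groups did not overlap, and chance gives 10%. The higher genes with the smallest p were GDF15, CD22, a surface protein of B cells, at 0.34 ± 0.046, and LHB at 0.34 ± 0.047. The Wnt-inactivating enzyme NOTUM at 0.27 ± 0.039 and CITED4, a transcriptional cofactor, at 0.45 ± 0.069 completed this set. Their adjusted p-values ran from 0.113 to 0.143. LHB encodes the beta subunit of luteinizing hormone and is near-identical to the chorionic gonadotropin beta genes, so its value is uncertain. Those lower were the taste receptor gene TAS2R50 at -0.37 ± 0.047, the chemokine receptor CCR7 at -0.36 ± 0.058, the aldo-keto reductases AKR1B10 at -0.40 ± 0.064 and AKR1B15 at -0.26 ± 0.046, and the small RNA SCARNA27 at -0.32 ± 0.058. Their adjusted p-values ran from 0.113 to 0.201. Of the genes chosen for naming in advance, ERVFRD-1 differed by 0.09 ± 0.123, GCM1 by 0.05 ± 0.045, OVOL1 by 0.07 ± 0.047, NR4A3 by -0.01 ± 0.065, and STAT5B by 0.11 ± 0.048 log2. ERVW-1 differed by -0.01 ± 0.070, RAPGEF3 by -0.00 ± 0.062 and PRKACA by 0.05 ± 0.043 log2. The median 95% confidence interval of a gene reached 0.12 log2, or 1.09-fold, to either side of its estimate. In simulated data, 100 of 100 genes changed by 0.5 log2 were recovered but only 35 of 100 changed by 0.25 log2. Changes of that size could thus go uncalled. Those data held many changed genes at once, which eases the adjusted threshold, and noise independent between genes. On the real arrays CITED4, at 0.45, was not called in this fit, so larger changes could go uncalled too. Some settings did give calls, namely 4 genes with an intensity trend (GDF15, CD22, LHB and NOTUM, each at an adjusted p of 0.0401) and 185 genes with array weights, among them CGA at 0.38 and all 10 genes with the smallest p named above. There was 1 gene without replicate 1 of the PKA-selective analog (PADI1, at 0.42), and 1 with the 25th percentile of each array as a covariate, a setting chosen after seeing the data (AKR1B10, at -0.39).

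In camera with its preset correlation 9 of the 22 lists passed with the EPAC-selective analog, 6 upward and 3 downward, and with an estimated correlation, as with fry, only the extravillous trophoblast markers did. In that list 18 of 21 genes lay above 0, 8 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.13e-09, and adjusted p = 0.0126 with an estimated correlation). It passed in all 21 other settings, with a median from 0.04 over every row of the table to 0.10 without untreated replicate 2. ADAM19 stood at 0.27 ± 0.046, LAIR2 at 0.24 ± 0.046 and EBI3 at 0.21 ± 0.041 log2, none past the threshold over all genes, and HLA-G at -0.00 ± 0.057. Placental protein hormones had a median of 0.11 log2 over 12 genes, with 5 higher adjusted over the list alone (camera adjusted p = 3.73e-05, but adjusted p = 0.115 with an estimated correlation). Steroid synthesis genes had a median of 0.10 over 11 genes, all above 0, with 1 higher adjusted over the list alone (camera adjusted p = 9.35e-06, but adjusted p = 0.115 with an estimated correlation), and CYP11A1 stood at 0.24 ± 0.055. Pregnancy-specific glycoproteins had a median of 0.07 over 9 genes, with 1 higher adjusted over the list alone (camera adjusted p = 0.000692, but adjusted p = 0.115 with an estimated correlation). Cyclic AMP response element targets had a median of 0.04 over 25 genes, with 1 higher adjusted over the list alone (camera adjusted p = 0.000951, but adjusted p = 0.115 with an estimated correlation).

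Trophoblast transcription factors had a median of 0.04 over 21 genes with the EPAC-selective analog and 0 adjusted over the list alone (camera adjusted p = 0.0403, but adjusted p = 0.494 with an estimated correlation). Their call was lost, at medians of 0.01 to 0.04, without replicates 1 or 3 of the untreated cells or with any of the 3 arrays of this analog left out, and at 0.03 with centred arrays. Of the lists that passed downward, mitosis genes lay below 0 in 22 of 23 cases with 1 lower adjusted over the list alone, among them KIF20A at -0.20 ± 0.045 and TOP2A at -0.17 ± 0.067 (camera adjusted p = 2.62e-08, but adjusted p = 0.376 with an estimated correlation). Genes of DNA replication and S phase entry had a median of -0.04 over 22 genes (camera adjusted p = 0.00116, but adjusted p = 0.478 with an estimated correlation), and cholesterol synthesis and uptake a median of -0.05 over 19 genes (camera adjusted p = 0.00116, but adjusted p = 0.431 with an estimated correlation), each with 0 adjusted over the list alone. Without replicate 2 of the untreated cells both were no longer called, at medians of -0.02 and -0.03, and with array weights the cholesterol list had a median of 0.00. With array weights the DNA replication list, at -0.01, was not called either. The other 13 lists, including stromal, endothelial and blood cell markers at 0.01 log2 and EPAC and Rap signalling genes at -0.00, did not pass, with camera adjusted p-values of 0.0531 for the unfolded protein response to 0.996 for hypoxia and glycolysis genes. The unfolded protein response list, at a median of 0.03 log2, passed in 12 of 21 other settings, among them those without untreated replicate 2 (median 0.04, adjusted p = 0.00299), replicates 1 or 3 of the EPAC-selective analog (0.04) or replicates 1 or 3 of the PKA-selective analog (0.03), but not with an estimated correlation (adjusted p = 0.431) or fry (0.383). The CDK inhibitors passed with an intensity trend (0.0431) and with the 25th percentile covariate (0.0436), and had an adjusted p = 0.316 with an estimated correlation. Their median, mean and test differed in sign for cytotrophoblast markers, EPAC and Rap signalling, hypoxia and glycolysis, interferon-stimulated genes, epithelial junctions and housekeeping genes. Adjusted over the list alone, those 13 lists gave 1 CDK inhibitor higher and, among the transporters, 1 higher and 1 lower.

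**Figure D2:**
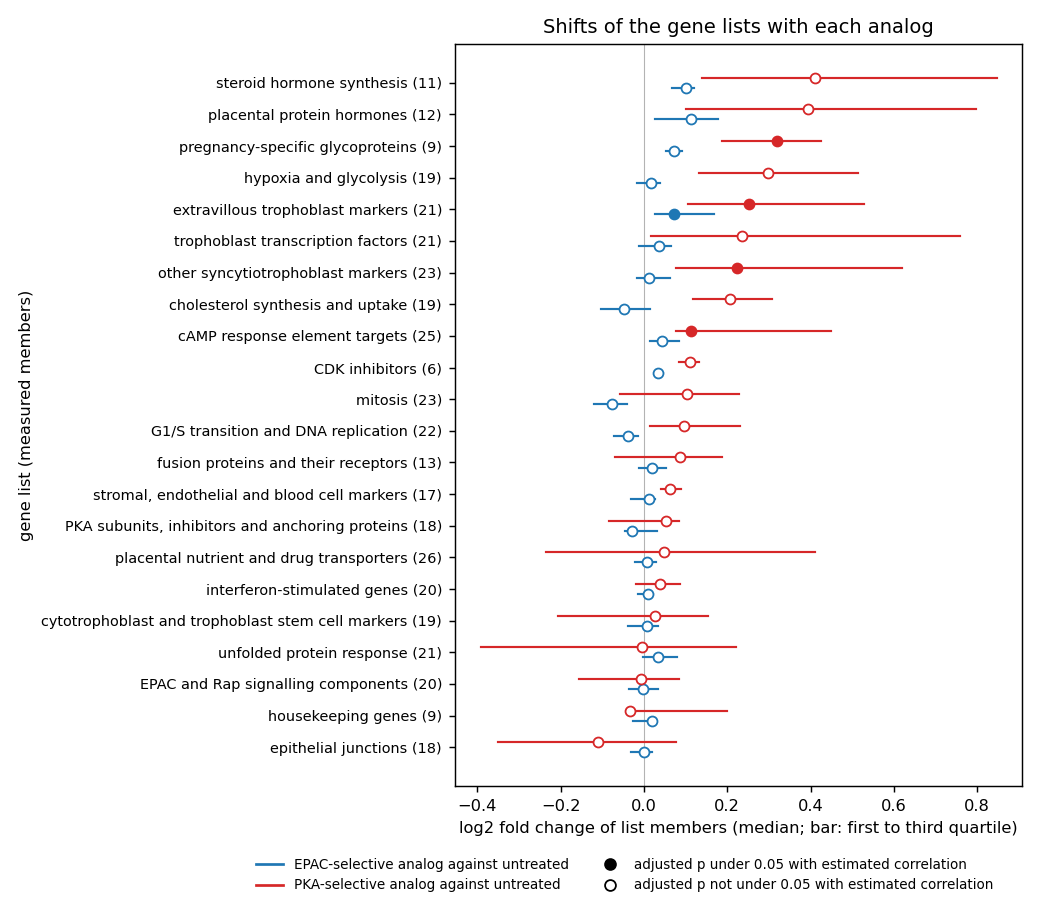
Median log2 fold change of the measured members of each of the 22 gene lists against untreated cells, with bars from the lower to the upper quartile of members; filled points mark lists past an adjusted p of 0.05 with an estimated correlation. The medians with the EPAC-selective analog run from -0.08 to 0.11, and those with the PKA-selective analog from -0.11 to 0.41.

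Set directly against each other at 48 h, the analogs differed at 4371 genes, 2023 higher and 2348 lower with the PKA-selective analog, in limma at an adjusted p of 0.05. LGALS16 was 5.15-fold higher with the N6-phenyl compound than with the C8-substituted one, at 2.36 ± 0.089 log2 (SE, n = 3 arrays per group, adjusted p = 6.90e-08), HSD11B2 4.77-fold, ERVV-2 4.29-fold, CGA 4.06-fold and ERVFRD-1 4.05-fold. SLC7A11 was lower by 5.56-fold and ASS1 by 4.07-fold. Since the doses are not given, the values compare the treatments and not the potency of the compounds.

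The same naming rule, which passes over microRNA genes and other classes, was used here. Among the 10 largest differences upward were also PADI1 at 1.82 ± 0.068, SLC7A8 at 1.78 ± 0.051 and ERVV-1 at 1.74 ± 0.122 log2. LEP at 1.73 ± 0.124 and TREML2 at 1.60 ± 0.081 log2 were among them too. Downward they were joined by ALDH1L2 at -1.88 ± 0.123, TFCP2L1 at -1.76 ± 0.051, SLC34A2 at -1.75 ± 0.098, ULBP1 at -1.72 ± 0.187, ASNS at -1.64 ± 0.184, KLHDC7B at -1.69 ± 0.061, the interleukin receptor IL20RB at -1.55 ± 0.082 and the glycine transporter SLC6A9 at -1.55 ± 0.078. At least a 2-fold difference was reached by 41 genes upward and 58 downward. Of the genes fixed for naming, GCM1 differed by 0.71 ± 0.045, OVOL1 by 1.21 ± 0.047, STAT5B by 0.85 ± 0.048, and NR4A3 was 2.82-fold higher. ERVW-1 was lower by 1.21-fold, at -0.27 ± 0.070 (adjusted p = 0.0188), a call lost at -0.25 to -0.20 without replicates 1 or 2 of the EPAC-selective analog or replicate 1 of the PKA-selective analog, and also over every row of the table and, at -0.20, with the 25th percentile covariate. RAPGEF3 and PRKACA did not pass, although PRKACA did with array weights (0.11, adjusted p = 0.0176). The difference of RAPGEF3 was 0.08 with a 95% confidence interval from -0.06 to 0.22, and that of PRKACA 0.09 with an interval from -0.01 to 0.18 log2. These intervals bound the differences and do not show that the compounds act alike. CITED4, the gene with the largest of the EPAC-side values named above, differed by -0.51 ± 0.069 (adjusted p = 0.000377), and GDF15 was higher by 0.61 ± 0.042 (adjusted p = 3.55e-06).

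Of the 22 lists 13 passed between the analogs, 12 upward and 1 downward, and 3 of them also with an estimated correlation. Of 23 other syncytiotrophoblast markers 14 were higher and 1 lower, or 15 and 2 adjusted over the list alone, at a median of 0.25 log2 (camera adjusted p = 1.38e-07, and adjusted p = 0.0326 with an estimated correlation). That median ran from 0.23 to 0.56 over 21 other settings. Of 21 extravillous trophoblast markers 12 were higher and 0 lower, or 13 and 1 adjusted over the list alone, at a median of 0.21 (camera adjusted p = 4.86e-07, and adjusted p = 0.0303 with an estimated correlation). Of 25 cyclic AMP response element targets 11 were higher and 1 lower, or 12 and 1 adjusted over the list alone, at a median of 0.14 (camera adjusted p = 3.01e-06, and adjusted p = 0.0303 with an estimated correlation). The other lists that passed did so in camera only with the preset correlation, and all 13 passed with fry. Steroid synthesis had a median of 0.38 with 6 of 11 higher (camera adjusted p = 3.01e-06, but adjusted p = 0.0976 with an estimated correlation). Placental protein hormones had a median of 0.32 with 6 of 12 higher and 2 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.000428, but adjusted p = 0.137 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.30 with 13 of 19 higher and 1 lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 4.67e-07, but adjusted p = 0.0976 with an estimated correlation). Pregnancy-specific glycoproteins had a median of 0.25 with 5 of 9 higher, or 7 adjusted over the list alone (camera adjusted p = 3.89e-05, but adjusted p = 0.0671 with an estimated correlation). Trophoblast transcription factors had a median of 0.16 with 12 of 21 higher (camera adjusted p = 6.09e-07, but adjusted p = 0.0976 with an estimated correlation).

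Sterol, cell cycle and junction genes differed between the analogs as well. Cholesterol genes had a median of 0.21 with 12 of 19 higher and 1 lower, or 14 and 1 adjusted over the list alone (camera adjusted p = 4.86e-07, but adjusted p = 0.137 with an estimated correlation), with HMGCS1 higher by 0.87 ± 0.072 and INSIG1 by 0.85 ± 0.045. Mitosis genes had a median of 0.18 with 11 of 23 higher and 2 lower, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.000127, but adjusted p = 0.393 with an estimated correlation). DNA replication genes had a median of 0.13 with 8 of 22 higher, or 11 adjusted over the list alone (camera adjusted p = 5.59e-05, but adjusted p = 0.277 with an estimated correlation). Epithelial junctions had a median of -0.12 with 8 of 18 lower and 2 higher, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00312, but adjusted p = 0.226 with an estimated correlation). KIF20A differed by 0.52 ± 0.045, RRM2 by 0.69 ± 0.043 and OCLN by -1.02 ± 0.067. Stromal, endothelial and blood cell markers passed at a median of 0.08 (camera adjusted p = 0.0453, but adjusted p = 0.464 with an estimated correlation), with 4 of 17 higher. That call of the stromal list was lost at 0.06 to 0.09 without replicate 1 of the untreated cells, replicates 2 or 3 of the EPAC-selective analog or replicate 1 of the PKA-selective analog. It was also lost with an intensity trend (adjusted p = 0.0505), array weights (0.115), quantiles normalized again (0.0528), the mean of probe sets (0.0519) and the 25th percentile covariate (0.178), which took the median to 0.03. The 9 lists that did not pass had camera adjusted p-values from 0.0567 for EPAC and Rap signalling to 0.946 for interferon-stimulated genes, and fry called 5 of them: fusion proteins, EPAC and Rap signalling, CDK inhibitors, transporters and housekeeping genes. Over every row of the table camera also passed EPAC and Rap signalling (adjusted p = 0.0342) and transporters (0.0484).

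**Figure D3:**
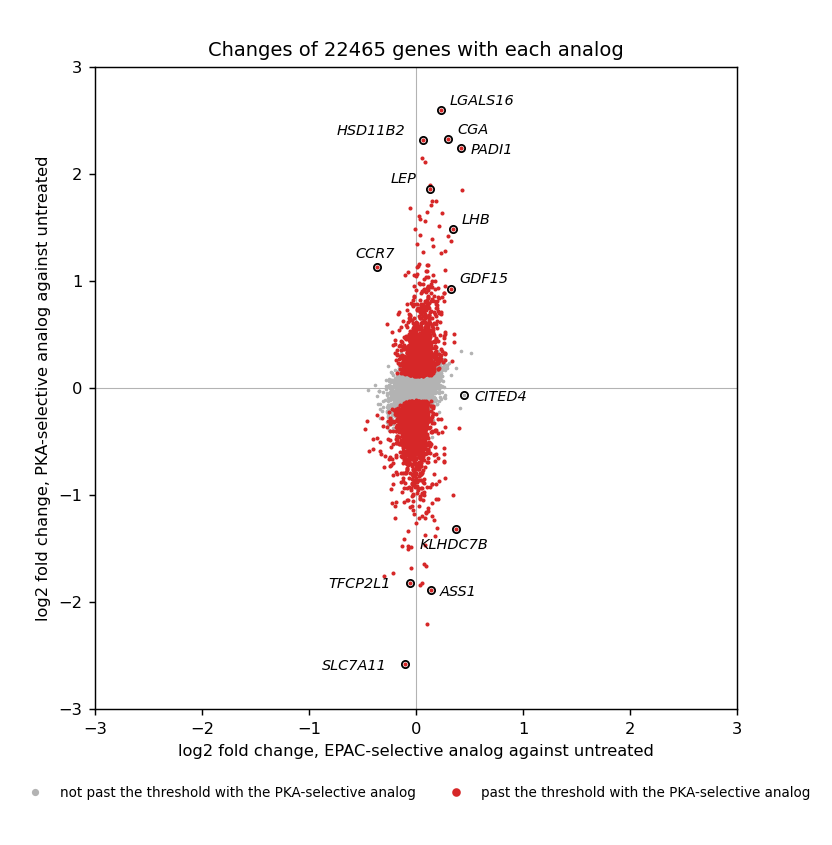
Log2 fold change against untreated cells with the EPAC-selective analog (horizontal) and the PKA-selective analog (vertical) for each of 22465 genes on equal axes; red points passed the adjusted p of 0.05 with the PKA-selective analog, and circles mark named genes. The points spread from -2.58 to 2.60 vertically and from -0.47 to 0.51 horizontally.

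Across genes, which are not independent replicates, the log2 changes with both analogs correlated at 0.303, and at 0.474 without untreated replicate 3. Both comparisons share the 3 untreated arrays, and unchanged groups simulated against such controls gave a median correlation of 0.609, with a range from -0.748 to 0.955. With the PKA changes kept and no EPAC change the simulated median was 0.146 and the highest value 0.551. The covariance was 0.00424 against a simulated median of 0.00218 and a highest value of 0.00879. The number of genes called in the same direction with both analogs was 0, where independent lists give 0 and the simulations gave at most 2. Since no gene was called with the EPAC-selective analog, this count had to be 0 and says nothing about a shared response. With 3 controls the untreated arrays could not be split into separate sets of at least 2, so part of any excess may come from the shared controls. KLHDC7B stood at 0.37 ± 0.061 with the EPAC-selective analog, not past the threshold, and fell by 1.32 ± 0.061 with the PKA-selective one. CCR7 stood at -0.36 with the former and rose by 1.13 ± 0.058 with the latter (adjusted p of the direct difference = 8.34e-08). KLHDC7B and CCR7 were singled out after their values were seen, so they do not show how the analogs relate. Of the genes with the smallest p named above, GDF15, CD22, LHB and NOTUM had all arrays of both analogs above all untreated arrays. TAS2R50, AKR1B10, AKR1B15 and SCARNA27 had them all below, while CITED4 and CCR7 followed neither pattern. These genes were chosen by their distance from the untreated arrays that both comparisons share, so this is no test of a shared response.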

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

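The covariate below and the unadjusted threshold were chosen only after the results were seen. No result changed its call in the opposite direction: over all settings 4285 values of named genes kept their side of the threshold, 17 passed newly and 53 no longer passed, and for lists these were 1290, 42 and 54; the cause was not tested unless stated. With array weights, which rested on untreated replicate 1 (3.48) and PKA-selective replicate 3 (5.47) against at most 1.33 elsewhere, the EPAC comparison gave 185 calls (119 higher, 66 lower), the PKA comparison 10934 (6509 and 4425), the direct comparison 8165 (4523 and 3642), a correlation between the analogs of 0.396 and 131 genes called the same way with both; 59.5% of PKA calls were higher, against 46.4% as reported and 40.4% with arrays centred on their medians. An intensity trend gave 4 EPAC calls, 4 higher, and 4 shared by both analogs. Over every row of the table, which adds rows, 4173 were lower with the PKA-selective analog and 3553 lower than with the EPAC-selective one. At least a 1.5-fold change left, by construction, 468 calls (202 and 266) and in the direct comparison 431 (176 and 255). Lists past the threshold numbered 1, 4 and 3 (EPAC, PKA, direct) with an estimated correlation, which widens the test, and 1 and 17 (EPAC, PKA) with fry. With each array's 25th percentile as a covariate the EPAC comparison gave 1 call, 1 lower, and 1 shared by both analogs. An unadjusted p under 0.05 gave 1096 EPAC calls (603 and 493). Leaving out 1 array gave 0 to 1 EPAC calls, 0 to 1 higher and 0 to 1 shared by both analogs, and correlations from 0.207 without EPAC-selective replicate 1 to 0.474 without untreated replicate 3. With the replicate number as a block the calls were 0 for EPAC, 5571 for PKA (2692 higher, 2879 lower) and 4738 directly (2265 and 2473), with 8, 11 and 13 lists, which kept 4925 of the 5031 PKA calls and 4279 of the 4371 direct ones. Of the named genes and lists only the EPAC transcription factor list was then not called (adjusted p = 0.0563). The labels do not say what an equal number in different groups marks. In their deviations from the group means, 4 of 9 same-numbered pairs correlated over 0.1, and 3 of 9 arrays correlated best with their own number. Replicate 2 pairs correlated at 0.324 (untreated, EPAC), 0.448 (untreated, PKA) and 0.230 (EPAC, PKA). However, untreated replicate 3 reached 0.479 with PKA-selective replicate 1, a pair of unequal numbers. The largest component of these deviations held 42.4% of their variance and correlated at 0.981 in size with each array's 25th percentile. That percentile was the lowest of its group at replicate 2, at 3.385, 3.408 and 3.421 (untreated, EPAC, PKA). It was the highest of its group at untreated replicate 3 and PKA-selective replicate 1. What sets this percentile was not tested, so a factor shared by the replicate 2 arrays stays open. Robust eBayes was not run for the lists, and fits of only the groups compared only for the counts of lists in the other splits. Background in dim genes limits what small changes can be seen.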

Other observations

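The 3 gene lists of this section and the splits counted over genes were chosen only after the results were seen. So were the tests with the 25th percentile covariate, with simulated noise, without replicate 1 of the PKA-selective analog and among bright microRNA genes. The p-values of the 3 lists were adjusted over these 3 lists alone within a comparison. Those p-values take no account of the choice from the same data, so they describe the lists and are no independent test.

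Genes of the amino acid response, most of them targets of the transcription factor ATF4, fell together with the PKA-selective analog. Of 33 measured 32 fell, at a median of -0.86 log2 (camera adjusted p = 2.71e-30, but adjusted p = 0.0610 with an estimated correlation). SLC7A11 stood at -2.58 ± 0.246, ALDH1L2 at -1.82 ± 0.123, ASNS at -1.68 ± 0.184, PSAT1 at -1.48, VLDLR at -1.47 and SLC6A9 at -1.46 log2, all past the threshold. The 3 treated arrays had medians of -1.03, -0.77 and -0.57 against the untreated mean. With the EPAC-selective analog the median was 0.02.

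MicroRNA genes of the large cluster on chromosome 19, which is expressed mainly in placenta, also fell with the PKA-selective analog. Of 33 measured 31 fell, at a median of -0.63 log2 (camera adjusted p = 7.15e-22, but adjusted p = 0.0610 with an estimated correlation), among them MIR516A1 at -1.12 and MIR525 at -1.10. Outside the cluster MIR222 stood at -2.20 ± 0.159 and MIR21 at -1.84 ± 0.080. Whether these probe sets read precursors or mature microRNAs was not tested. On the PKA-selective arrays the cluster had medians of -0.87, -0.51 and -0.58 against the untreated mean. With the EPAC-selective analog the cluster had a median of -0.12 (camera adjusted p = 2.67e-06, but adjusted p = 0.351 with an estimated correlation). Its arrays had medians of -0.15, -0.08 and -0.12 against the untreated mean. These lay within the range of the untreated arrays, which had 0.04, 0.13 and -0.17. Targets of NRF2 stood at a median of 0.01 and a mean of -0.17 with the PKA-selective analog, with the test pointing downward, 3 higher and 3 lower of 17 (camera adjusted p = 0.322), and of -0.03 with the EPAC-selective one (camera adjusted p = 0.0120, but adjusted p = 0.223 with an estimated correlation).

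The 49 genes at least 2-fold higher with the PKA-selective analog leaned higher with the EPAC-selective analog too, at a median of 0.10 log2 with 43 of 49 above 0. Chance values of the shared untreated arrays could produce such a lean, but 0 of 100 simulations without an EPAC effect reached it, and the highest gave 0.088. The simulations used only the spread within groups, so they hold no effect common to all arrays of a group. They also added noise to the measured PKA changes, which already hold that of the real untreated arrays, and selected genes by size alone. With so small a margin they leave chance open. With each array's 25th percentile as a covariate the median was 0.105, but the untreated and EPAC arrays differed in that percentile by only 0.0034 ± 0.023, so the covariate could not move it and array quality stays open. A weaker copy of the whole PKA response would lower the 53 genes at least 2-fold lower with PKA, whose median was 0.025 against a simulated SD of 0.074, so this test cannot tell. An effect of the EPAC-selective compound on part of these genes stays a hypothesis, and no biological explanation was tested.

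The fall of the amino acid response genes might rest on replicate 1 of the PKA-selective analog, the array where the median of these genes was lowest. Without that array the median log2 change of the list was still -0.672. With the 25th percentile as a covariate it was -0.727, so array quality measured in this way does not account for it. The amino acid supply of the cultures is not given in the sources used here, so it could not be tested.

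The fall of the chromosome 19 cluster could belong to a shift of microRNA genes in general, and the median of 0.029 of 998 other microRNA genes does not decide this, since their median untreated level was 4.56 against 6.19 in the cluster. Of these 998 genes 35 rose and 61 fell. Among the 371 with an untreated level at or above the cluster's lower quartile the median was 0.047 with an SD of 0.249, where a shared shift would need at least -0.314, which argues against one shift of all microRNA genes of that brightness. A change shared by only some of them stays open, since 39 of the 371 fell and 16 rose. With the 25th percentile as a covariate the cluster's median was -0.484.

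The 6 arrays of a comparison can be divided into groups of 3 in 10 ways, and 10 splits cannot give a share under 0.05. The counts come from fits of only the groups compared and so differ from those of the report, and they use the preset correlation for lists. In the EPAC comparison all 10 splits, the real one included, gave 0 genes. The real split gave 10 lists and the others at most 5. In the PKA comparison the real split gave 4041 genes and 11 lists, the others 0 genes and at most 8 lists. Between the analogs the real split gave 4575 genes and 13 lists, the others 0 genes and at most 9 lists. Each other split holds arrays of both conditions in each group, so a treatment effect adds to its spread within groups. Their 0 genes in the PKA and direct comparisons therefore say little about chance.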
